A study of Arabidopsis thaliana with 18 samples.

How the data were processed

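Small RNA was sequenced from inflorescences of Arabidopsis thaliana of the Columbia accession in 18 libraries, made of 6 genotypes with 3 biological replicates each. The genotypes were wild type, frg1 frg2 (written frg1/2), a mutant in FRG1 to FRG5 (frg1to5), suvr2, drm1 drm2 (drm1/2) and dcl3. Per the labels, RNA was extracted with TRIzol, precipitated with PEG and NaCl, selected by size on a gel, and made into TruSeq small RNA libraries by PCR. The reads carried no molecular identifiers, so intervals and floors given for counts cover counting error only.

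The deposited files gave, for each library, every distinct trimmed sequence of 9 to 40 nt with its raw number of reads (counts), without normalization, mapping or annotation. The authors' notes name Bowtie without a version and the TAIR10 genome, but the deposited counts carry no mapping, and the trimming tool is not stated. All mapping and annotation used here was therefore done anew.

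Reads of 18 to 30 nt were matched to the TAIR10 nuclear and organelle sequences, and only matches without a mismatch were kept. A read was classed as structural if the middle of any match lay in an rRNA, tRNA, snRNA or snoRNA gene, then as organellar, and otherwise as genome-matched. The 25S rRNA was taken as the 3600 bp after the 5.8S gene, and the 5S arrays were not annotated and were not removed. The annotation in hand held transposon genes and pseudogenes but not transposons as such, so no class of transposon families was formed.

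Reads of exactly 24 nt with a single genome match, and separately reads of 21 or 22 nt, were counted by their 5′ end in fixed windows of 500 bp. They were also counted over gene regions, each an annotated gene with the 1000 bp upstream of it. Windows were classed by whether their midpoint lay in coding genes, pseudogenes and transposon genes, other genes, in the 1000 bp upstream of coding genes, or in none of these (intergenic). The chromosomes were cut in 240 segments of 500 kb, and the 46 segments (23.0 Mb) whose share of coding exons was under 1/2 of the median segment's 45.3% were called pericentromeric. Mature miRNAs were counted as exact sequences from a fixed list. CPM (counts per 1e6) use the total of genome-matched 18- to 30-nt reads of each library, without further scaling of windows or gene regions, so that a genome-wide loss of 24-nt reads stays visible. The miRNA test used the total of the listed miRNA reads with edgeR's TMM scaling over the miRNAs, and miRNA levels are given per 1e6 of that scaled total.

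Total reads ranged from 13.8 to 22.9 M (M for 1e6) per library and genome-matched reads from 6.27 to 12.4 M. A count of 0 allows up to 3 counts, which corresponds to 0.241 to 0.479 CPM per library. Where a group had no read in any of its 3 libraries, the fold was computed against 3 counts over the group and given as a lower bound. With 1 to 3 reads in a group, the reads are given, for part of the features with the ratio of pooled CPM and its exact 95% counting interval. Levels are means with the SD of 3 libraries.

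Counts were tested with edgeR 4.0.16 (quasi-likelihood fit and test, R 4.3.3) in a fit of all 18 libraries with 1 shared estimate of spread and no replicate block. Features needed at least 1 CPM in at least 3 libraries, and Benjamini-Hochberg adjusted p below 0.05 was the threshold. Each mutant was compared with wild type, and frg1to5, suvr2, drm1/2 and dcl3 with frg1/2, as well as drm1/2 with suvr2. Shares of reads were compared by exact two-sided permutation tests, which with 3 against 3 libraries cannot give a p below 0.1. Gene lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and with an estimated one. DESeq2 1.42.0, pandas 2.3.3, numpy 2.4.6 and Python 3.11.15 were also used. These comparisons, the window sizes, filters, lists and the alternatives were fixed before the data were examined, except for those named below.

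Genes were named by a rule fixed in the same way. For each comparison with wild type it takes up to 10 gene regions with the largest fall and up to 10 with the largest rise in 24-nt reads. They needed an adjusted p below 0.05, an absolute log2 fold change of at least 1, a mean of at least 5 CPM over the 18 libraries, and all 3 mutant libraries outside the range of the wild type libraries. Of overlapping regions, only the one with the highest mean was kept. The rule also takes the members of the fixed lists, up to 5 miRNAs per direction past the threshold, up to 5 windows per direction under the same conditions in every comparison, and the mutated genes in every library. The fixed gene lists were the mutated genes, genes with known regulation by RNA-directed DNA methylation (RdDM), transposon genes, silencing machinery genes, TAS loci, and genes with miRNA- or tasiRNA-triggered siRNAs. The fixed miRNA lists were development, young miRNAs, silencing and stress. Features named outside this rule are said to be so.

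The calculation was tested on simulated data in which 200 features (8 miRNAs) were changed 2- or 4-fold between frg1/2 and wild type. It recovered 48% and 83% of the changed 24-nt windows, 24% and 79% of 21- to 22-nt windows, 62% and 92% of 24-nt gene regions, and 34% and 86% of 21- to 22-nt gene regions. Of 4 miRNAs changed 2-fold it recovered 2, and of 4 changed 4-fold it recovered 3. Among the features left unchanged, it called 6 of the 24-nt windows, 8 of the 21- to 22-nt windows, 11 of the 24-nt gene regions, 8 of the 21- to 22-nt gene regions and no miRNA, and it called none between simulated groups that did not differ.

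The alternatives were other library sizes (TMM factors, DESeq2 size factors, the miRNA total, and all reads of the file), no filter, reads with several matches counted as 1/n per match, windows of 200 and 1000 bp, reads of 23 and 24 nt together, a DESeq2 Wald test, a fit of only the groups compared, a replicate block, a minimum fold change of 2, miRNAs with up to 2 nt added or missing at the 3′ end, and leaving out each replicate. For shares of reads, other denominators were used. Added after the data were seen were fits without the 3 libraries in which more than 10% of reads had 33 to 34 nt, and the counts of 21- to 22-nt reads over the gene regions of the lists with their alternatives. All mutants were compared with the same 3 wild type libraries, which are too few to split, so covariances and correlations of log2 fold changes between mutants were set beside those of 10 simulations of unchanged groups sharing 1 control. Such groups hold no called windows, so the simulations give no value for overlaps of called windows.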

Results

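Small RNA from inflorescences was sequenced for wild type and 5 mutant genotypes of Arabidopsis, with 3 biological replicates per genotype. The study asks whether FRG1 and FRG2, proteins with SNF2 and RING domains, act in RdDM, the pathway in which small RNAs guide DNA methylation. DCL3 makes the 24-nt siRNAs of that pathway, DRM1 and DRM2 are DNA methyltransferases, and SUVR2 is a SET-domain protein linked to the pathway. Wild type libraries held 14.2 to 19.0 M reads (M for 1e6), frg1/2 13.8 to 15.4 M, frg1to5 14.3 to 16.8 M, suvr2 16.2 to 21.7 M, drm1/2 20.6 to 21.9 M and dcl3 18.5 to 22.9 M. Single-match 24-nt reads numbered 3.41 to 5.85 M per library outside dcl3 and 0.293 to 0.488 M in dcl3. Levels below are mean CPM with the SD of 3 libraries per genotype, and fold changes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

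The mutated genes themselves gave few small RNAs, and these reads do not check the mutations. FRG1 (AT3G20010) had no 24-nt read in wild type, 13, 3 and 12 reads in the frg1/2 libraries and 16, 13 and 16 in the frg1to5 libraries. This was at least 10.8-fold and at least 16.5-fold higher than wild type (edgeR adjusted p = 6.54e-05 and 2.66e-06). FRG2 (AT1G50410) had 2, 3 and 1 reads in wild type, 6, 7 and 4 in frg1/2 and 10, 12 and 16 in frg1to5. In suvr2, FRG1 had 3, 0 and 2 reads and FRG2 6, 9 and 7; in drm1/2 they had 4, 1 and 2 reads and 4, 4 and 6, and in dcl3 1, 1 and 0 and 2, 3 and 2. DCL3 (AT3G43920) had 67, 88 and 69 reads of 24 nt in wild type and 15, 13 and 11 in dcl3, while its 21- to 22-nt reads rose from 5, 7 and 4 to 64, 51 and 44. DCL3 24-nt reads also fell in drm1/2 (17, 24 and 11 reads, log2 fold change -2.20 ± 0.19 SE, adjusted p = 2.17e-11) and in suvr2 (38, 27 and 50 reads, -0.89). SUVR2, DRM1 and DRM2 had at most 12 reads of 24 nt in any library, with 3, 2 and 3 over DRM1 and 10, 12 and 9 over DRM2 in drm1/2.

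The 24-nt class made up 60% ± 1.23 (SD, n = 3) of genome-matched reads in wild type and 5.93% ± 0.165 in dcl3, a difference of -54.1 points (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow). It was 60.2% ± 1.51 in frg1/2, 59.1% ± 0.820 in frg1to5, 60.7% ± 0.915 in suvr2 and 57.8% ± 2.88 in drm1/2 (exact p = 0.9, 0.4, 0.5 and 0.3), or 0.24, -0.86, 0.75 and -2.21 points from wild type. As a share of all reads these differences were -1.76, -2.18, -5.07 and -8.37 points, and -35.4 in dcl3. Among single-match reads frg1/2 (-0.55) and suvr2 (-1.97) also turned negative, while suvr2 was 2.99 points above wild type as a share of 21- and 24-nt reads. In dcl3 the 21-nt share was 35.0% ± 2.77 and the 22-nt share 24.1% ± 0.328, against 17.5% ± 0.783 and 6.29% ± 0.366 in wild type (exact p = 0.1 for each). The 22-nt share was also above every wild type library in frg1/2 (6.86% ± 0.134), frg1to5 (6.88% ± 0.158), suvr2 (7.57% ± 0.448) and drm1/2 (7.45% ± 0.472), each with an exact p of 0.1. The 23-nt share was 8.46% ± 0.694 in drm1/2 and 9.58% ± 0.288 in frg1to5 against 10.8% ± 0.450 in wild type (exact p = 0.1 for each). Among 24-nt reads, 58.5% ± 0.893 began with A in wild type and 46.2% ± 0.707 in dcl3 (exact p = 0.1). The share beginning with G was 13.0% ± 0.734 in wild type and 35.2% ± 1.59 in dcl3, and the shares of C and T were lower in dcl3 (exact p = 0.1 for each). In suvr2 the 21-nt share was 14.8% ± 1.43 (exact p = 0.1), and the listed miRNAs took 9.38% ± 1.56 of genome-matched reads against 13.0% ± 0.874 in wild type (exact p = 0.1). Replicates 2 and 3, with 19.1% and 5.68% of all reads at 33 to 34 nt, carried most of both differences: 14.3% and 13.7% at 21 nt and 8.50% and 8.47% for miRNAs, against 16.4% and 11.2% in replicate 1. The lowest miRNA shares of frg1/2 (10.2%), drm1/2 (9.38%) and dcl3 (9.31%) were likewise in the libraries with most reads of 33 to 34 nt, replicate 3 of each.

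**Figure D1:**
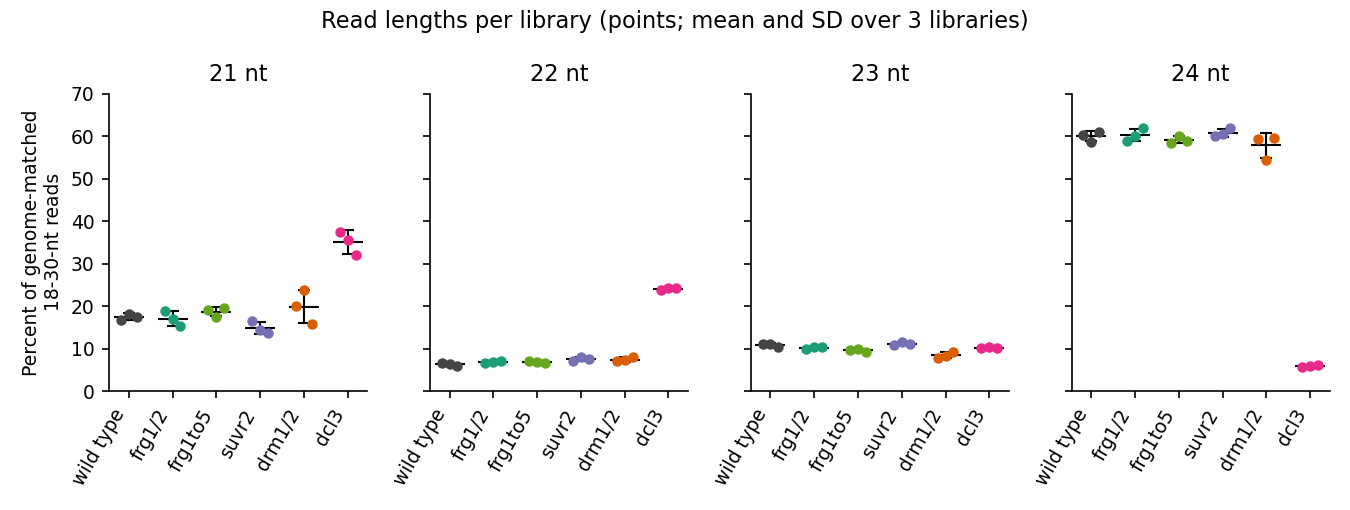
Percent of genome-matched 18- to 30-nt reads (y axis) of 21, 22, 23 and 24 nt (panels) in each genotype (x axis), with 1 point per library and the mean and SD over 3 libraries in black. The 24-nt share was 5.93% in dcl3 and between 57.8% and 60.7% in the other genotypes, while the 22-nt share was 24.1% in dcl3 and 6.29% in wild type.

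The comparison of frg1/2 with wild type asks where loss of FRG1 and FRG2 alters 24-nt siRNAs. At ILA (AT1G64790, chromosome 1, 24064822 to 24083428), which encodes a HEAT-repeat protein, 24-nt reads fell from 95.7 ± 12 to 0.492 ± 0.187 CPM (log2 fold change -7.57 ± 0.20 SE, adjusted p = 7.48e-22). A window in ILA held far more 24-nt reads in frg1to5 than in frg1/2 (below), although FRG1 and FRG2 are mutated in both. The fall at ILA can therefore not be credited to loss of FRG1 and FRG2 alone. At YUC2 (AT4G13260, chromosome 4, 7721487 to 7724070), an auxin biosynthesis enzyme, they fell from 25.4 ± 2.77 to 0.593 ± 0.216 CPM (-5.37 ± 0.33, adjusted p = 1.49e-13). AT3G44580 on chromosome 3 fell from 303 ± 21 to 24.1 ± 1.69 CPM (-3.65 ± 0.17, adjusted p = 2.55e-16). Other loci gained 24-nt reads: the pseudogene AT1G64035 (chromosome 1, 23755496 to 23757736) rose from 0.577 ± 0.104 to 86.7 ± 11.1 CPM (7.18 ± 0.23, adjusted p = 7.39e-20), and PKS1 (AT2G02950), a phytochrome-interacting protein, from 3 to 983 reads (a ratio of 379, counting interval 129 to 1841).

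AT1G29550 and AT1G75945 kept 3 reads each in the 3 frg1/2 libraries against 741 and 484 in wild type, ratios of 213 (95% counting interval 72.8 to 1038) and 139 (47.4 to 679). Other falls were at AT1G08673 (-6.64), AT4G10200 (-6.12), AT5G07295 (-5.89), AT3G28330 (-5.02) and AT5G03000 (-3.67 on the log2 scale). EMB2816 (AT2G03870) rose from 4.01 ± 1.19 to 178 ± 45.0 CPM (5.45 ± 0.36, adjusted p = 9.68e-13) and ASY2 (AT4G32200), a paralogue of a meiotic chromosome axis protein, from 0.681 ± 0.115 to 29.6 ± 8.31 CPM (5.41 ± 0.32, adjusted p = 1.03e-13). NAC089 (AT5G22290), a transcription factor, rose from 2 to 506 reads (a ratio of 293, 80.6 to 2424) and AT3G07085 from 1 to 573 reads (663, 119 to 26229). Further rises were at AT5G20090 (6.91), AT5G20740 (6.04), AT3G09970 (5.79) and AT4G06805 (4.94). Among windows, the 500 bp from 7378001 on chromosome 5, upstream of NAC089, went from no read to 18.4 ± 0.642 CPM (at least 188-fold higher). The window from 16584001 on chromosome 3, at AT3G45250, went from no read to 19.2 ± 1.79 CPM (at least 197-fold higher). In the window upstream of EHD2 (chromosome 4, from 2804001), 3 reads remained of 1240.

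Of 37670 windows tested in frg1/2, 3765 (9.99%) fell and 1303 (3.46%) rose, 1699 and 760 of them by at least 2-fold. Of 11448 gene regions, 1943 fell and 594 rose. Windows upstream of coding genes fell in 1006 of 5205 cases (19.3%), and pseudogene and transposon gene windows in 194 of 11272 (1.72%). In the chromosome arms 2567 of 16310 windows fell (15.7%) and in the pericentromeres 1198 of 21360 (5.61%). The median of all windows was -0.11, and it was 0.00 with TMM factors, 0.01 with the miRNA total and -0.19 with all reads as library size. With TMM factors 2767 windows fell and 1723 rose, and 1507 and 771 gene regions, while the miRNA total gave 1104 and 802 windows. Medians of the pericentromeric windows (-0.10) and of pseudogene and transposon gene windows (-0.04) turned positive with TMM factors (0.01 and 0.07), and that of upstream windows (-0.19) stayed negative under all 4 other scalings.

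Of the silencing machinery list, 13 of 34 regions had enough 24-nt reads, and 4 fell and 2 rose (the same counts adjusted over the list alone). SUVH9 (AT4G13460), which helps recruit RNA polymerase V, fell from 25.2 ± 8.89 to 0.769 ± 0.397 CPM (-5.05 ± 0.34, adjusted p = 1.18e-12). NRPD2 (AT3G23780), a subunit of RNA polymerases IV and V, fell from 3.30 ± 1.34 to 0.191 ± 0.0744 CPM (-4.01, adjusted p = 6.42e-07). CLSY4 (AT3G24340), a chromatin remodeller of the pathway, fell by 1.40 and DCL4 (AT5G20320) by 0.45 on the log2 scale. MORC6 (AT1G19100), an ATPase in gene silencing, rose from 0.121 ± 0.105 to 10.9 ± 0.469 CPM (6.26 ± 0.38, adjusted p = 1.51e-13). Of 11 genes with RdDM-linked regulation, FWA fell (-0.53) and ROS1 (0.81) and EPF2 (1.58) rose, also when adjusted over the list alone, and ROS1 was -0.15 with reads of several matches counted 1/n. None of the 3 transposon genes and 7 TAS loci tested changed in edgeR, and of 6 genes with triggered siRNAs AFB3 rose (0.65). In the mutated gene list, 2 of 3 tested members rose (3 adjusted over the list alone). No list differed from other regions in camera (smallest adjusted p = 0.0501, for the mutated genes, and 0.124 with an estimated correlation).

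**Figure D2:**
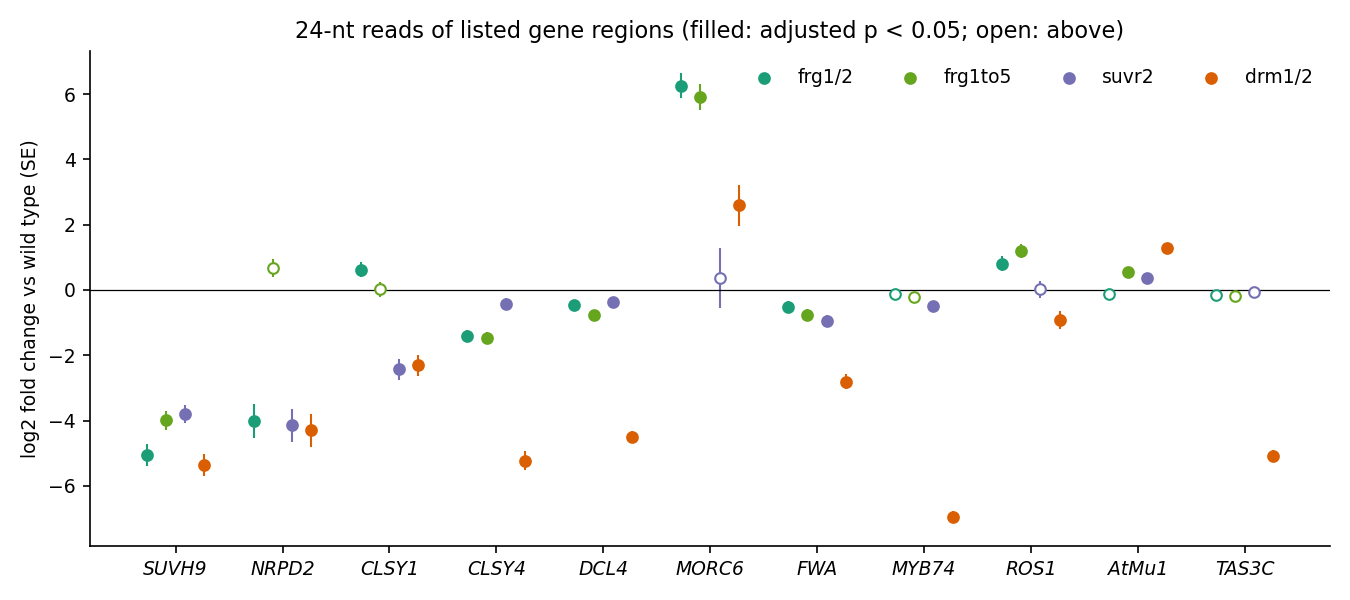
Log2 fold change against wild type (y axis, with SE) of 24-nt reads over 11 gene regions of the fixed lists (x axis) in 4 mutants of 3 libraries each, filled where the adjusted p was below 0.05 and open where above. All regions shown passed that threshold in a mutant of the figure, and tested list members that passed in none were left out. SUVH9 fell in all 4 mutants (-3.80 to -5.36), while MORC6 rose by 6.26 in frg1/2 and 5.92 in frg1to5 and MYB74 fell by 6.96 in drm1/2.

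Of 18026 windows tested for 21- to 22-nt reads in frg1/2, 245 fell and 302 rose, and leaving out 1 library brought the 547 to between 298 and 480. Of windows with lower 24-nt reads that could be tested for both, 230 of 2085 (11%) also passed as lower for 21- to 22-nt reads and 2 as higher. The median of these 2085 windows was -0.63 for 21 to 22 nt and -0.76 for 24 nt, and that of windows with unchanged 24-nt reads was 0.01 for 21 to 22 nt. Where 24-nt reads rose, 268 of 715 (37.5%) also had higher 21- to 22-nt reads.

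A pair of neighbouring genes, AT3G44570 and AT3G44580, gave among the most abundant small RNAs lost, and AT3G44570 was chosen after its values were seen. Over their span (chromosome 3, 16158405 to 16161837, 3433 bp), 24-nt reads were 566 ± 34.3 CPM in wild type, 33.1 ± 3.83 in frg1/2 and 34 ± 6.47 in frg1to5, or 5.84% and 6.01% of wild type. They were 573 ± 25.8 CPM in suvr2, 801 ± 38.2 in drm1/2 and 59.9 ± 10 in dcl3. The 21-nt reads were 240 ± 4.43 CPM in wild type, 5.00 ± 1.56 in frg1/2 and 403 ± 37.8 in dcl3, and the 22-nt reads 294 ± 16.4, 6.23 ± 1.64 and 589 ± 9.45 CPM.

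**Figure D3:**
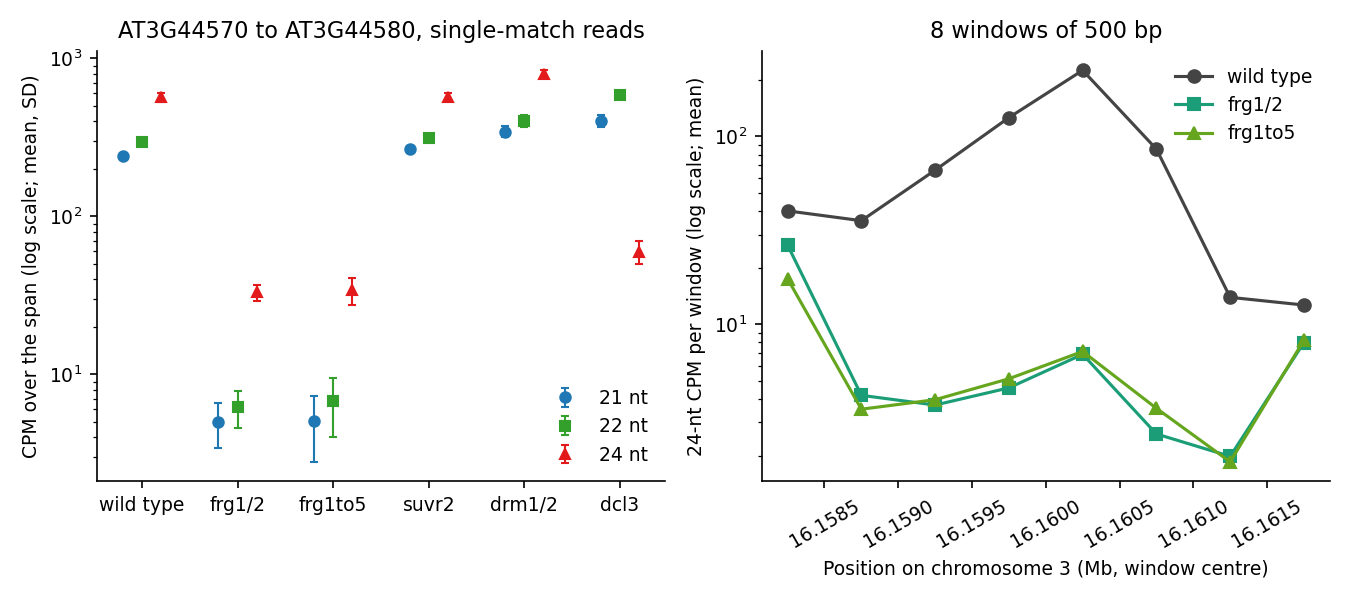
Left, CPM (y axis, log scale) of 21-, 22- and 24-nt reads over AT3G44570 and AT3G44580 in each genotype (x axis), mean and SD of 3 libraries; right, mean CPM of 24-nt reads (y axis, log scale) in 8 windows of 500 bp along chromosome 3 (x axis) in wild type, frg1/2 and frg1to5. In frg1/2, 24-nt reads over the span were 5.84% and in frg1to5 6.01% of wild type, while in suvr2 they were 573 CPM against 566 in wild type.

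The comparison of frg1to5 asks what is altered when FRG3, FRG4 and FRG5 are mutated as well. DYL1 (AT1G28330) rose from 3 to 1557 reads of 24 nt (a ratio of 571, counting interval 195 to 2773). YUC2 again fell, to 0.499 ± 0.403 CPM (-5.63 ± 0.33, adjusted p = 6.00e-14), and SBT5.4 (AT5G59810), a subtilisin-like protease, fell from 27.5 ± 5.09 to 0.604 ± 0.504 CPM (-5.46). DCL1 (AT1G01040), which makes miRNAs, rose from 0.452 ± 0.167 to 32.6 ± 27.8 CPM (6.13 ± 0.59, adjusted p = 1.61e-09), in the window from 22501 on chromosome 1 just upstream of the gene. Its libraries differed widely, and without frg1to5 replicate 2 the change of AT1G01040 was 5.23. SUVH9 fell (-4.00, adjusted p = 5.02e-12) and MORC6 rose (5.92, adjusted p = 8.24e-13), as they had in frg1/2.

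Other regions that fell in frg1to5 were AT1G29550 (2 reads against 741), AT4G10200 (-7.12), AT1G08673 (-6.71), AT3G28330 (-6.36), AT1G69610 (-6.08), AT1G48330 (-5.80), AT2G41650 (-5.17) and ESE2 (-4.41). Rises took in PKS1 (18.6 ± 4.70 CPM), NAC089 (17.0 ± 1.35 CPM), AT1G64035 (7.05), AT5G20090 (6.81), AT4G01020 (6.52), AT5G20740 (6.03) and ASY2 (5.24). Of the silencing machinery list 3 regions fell (SUVH9, CLSY4 and DCL4) and 3 rose (DCL1, MORC6 and SUVH2), or 3 and 4 adjusted over the list alone. NRPD2, which fell in frg1/2, was 0.66 ± 0.28 on the log2 scale in frg1to5 (adjusted p = 0.0700), a difference between the mutants that was not tested for the region. Of the RdDM-linked genes FWA fell (-0.77) and ROS1 (1.20), EPF2 (1.85), SDC (0.36) and HISN6B (0.51) rose, also when adjusted over the list alone. AtMu1, a Mutator transposon gene, rose (0.55, adjusted p = 2.00e-03), no TAS locus changed, AT1G62930 fell (-0.72) among genes with triggered siRNAs, and 2 of 3 mutated genes rose. No list stood apart in camera (smallest adjusted p = 0.0748, and 0.160 with an estimated correlation).

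In frg1to5, 6106 windows (16.2%) fell and 1829 (4.86%) rose, 3173 and 827 of them by at least 2-fold, and 2782 gene regions fell and 881 rose. Windows upstream of coding genes fell in 27.4% of cases, arm windows in 22.2%, pericentromeric windows in 11.7%, and pseudogene and transposon gene windows in 3.95% (445 lower and 336 higher, which turned to 266 and 759 with TMM factors). The median of all windows was -0.13, and it was 0.02 with TMM factors and -0.22 with the miRNA total. TMM factors gave 4505 windows lower and 3068 higher, and 2191 and 1407 gene regions. For 21- to 22-nt reads, 617 windows fell and 331 rose (948 in all, and 509 to 869 with 1 library left out). Compared directly with frg1/2, 863 windows were lower and 382 higher in frg1to5 (620 and 143 with the miRNA total), and 36425 did not pass. The direct test does not say which of the mutants departs from wild type, and the ILA region had fallen in frg1/2 (above). The window from 1544001 on chromosome 1 at AT1G04387 had 190 ± 19.4 CPM in frg1to5 and 0.308 ± 0.185 in frg1/2 (9.24 ± 0.28, adjusted p = 2.18e-35). The window from 24082501 on chromosome 1 in ILA had 23.6 ± 1.05 CPM in frg1to5 and 0.223 ± 0.100 in frg1/2 (6.63 ± 0.32, adjusted p = 7.10e-25). The window from 17363501 on chromosome 2 near AT2G41640 was lower in frg1to5 (0.468 ± 0.133 against 16.0 ± 1.10 CPM, -5.07 ± 0.30, adjusted p = 9.22e-21), as was that of MRD1 (-3.92). The window upstream of DCL1 was higher (7.63 ± 0.55, adjusted p = 1.49e-16). Leaving out frg1to5 replicate 3 brought the number of differing windows from 1245 to 730.

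**Figure D4:**
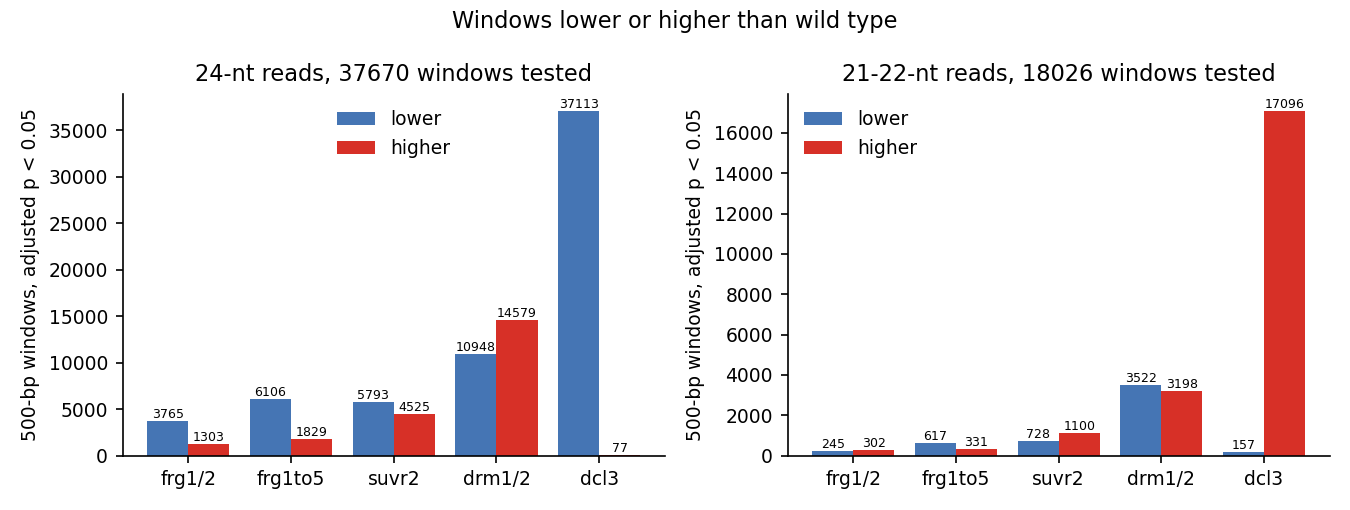
Number of 500-bp windows (y axis) that were lower (blue) or higher (red) than wild type at an adjusted p below 0.05 in each mutant (x axis), for 24-nt reads and for 21- to 22-nt reads (panels), 3 libraries per genotype. In dcl3, 37113 windows were lower for 24-nt reads and 17096 higher for 21- to 22-nt reads; with TMM factors these were 3587 and 1586, and for drm1/2 the 24-nt windows turned from 10948 lower and 14579 higher to 11957 and 10107.

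The comparison of suvr2 with wild type asks which 24-nt siRNAs need SUVR2, and several genes lost nearly all of theirs. At MEF14 (AT3G26780, chromosome 3, 9848628 to 9850543), a mitochondrial RNA editing factor, they fell from 239 ± 16.2 to 0.751 ± 0.382 CPM (-8.24 ± 1.01, adjusted p = 9.39e-08). At MYB3R-5 (AT5G02320), a transcription factor of the cell cycle, they fell from 159 ± 11.2 to 0.786 ± 0.310 CPM (-7.70 ± 0.25, adjusted p = 4.05e-20). At LIS (AT2G41500), a splicing factor, they fell from 79.6 ± 3.94 to 0.374 ± 0.332 CPM (-7.56 ± 0.24, adjusted p = 2.89e-20). Of 21360 pericentromeric windows 3123 rose and 1211 fell with the library sizes used, but 1714 and 1613 with DESeq2 size factors, 7677 and 400 with the miRNA total and 654 and 1395 with all reads. Their median was 0.28 (0.07 to 0.76 under the other scalings).

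Further falls in suvr2 were at AT5G07295 (-8.86), AT3G46570 (-8.19), AT1G08247 (-8.13), PRMT6 (-7.33) and AT2G04820 (-7.14), and AT2G08735 and AT2G06995 kept 2 reads each against 617 and 317. AT3G09970 rose from 0.319 ± 0.0779 to 20.9 ± 0.980 CPM (5.95), AT1G64035 to 12.4 ± 2.03 CPM (4.37 ± 0.28, adjusted p = 1.08e-13) and AT5G20740 to 12 ± 1.41 CPM (5.29). The glutamine synthetase gene GSR 1 (AT5G37600) rose from 6.93 ± 1.89 to 26.6 ± 4.47 CPM (1.93 ± 0.19, adjusted p = 1.97e-09), and the other named rises, at AT4G30740, AT5G17470, AT3G28540, AT2G09810, AT3G16930 and AT2G05015, were 1.57 to 2.49. Of 13 silencing machinery regions 5 fell and none rose at an adjusted p below 0.05 in edgeR, with the same counts adjusted over the list alone. They were SUVH9 (-3.80, adjusted p = 3.51e-12), NRPD2 (from 3.30 ± 1.34 to 0.168 ± 0.0304 CPM), CLSY1 (-2.44), CLSY4 (-0.41) and DCL4 (-0.38). Of the RdDM-linked genes FWA (-0.96), SNC1 (-0.86) and MYB74 (-0.48) fell and ALN rose (0.94, adjusted p = 4.19e-05). AtMu1 (0.38) and CACTA1 (0.35) rose among 3 transposon genes, no TAS locus changed, and of the genes with triggered siRNAs AT1G63080 rose (1.34) and AT1G62930 fell (-1.33). Of the mutated genes FRG1 and FRG2 rose and DCL3 fell. The same list members were called adjusted over the list alone, and in camera no list had an adjusted p below 0.823.

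In suvr2, 5793 windows (15.4%) fell and 4525 (12%) rose, 3410 and 1241 of them by at least 2-fold, as did 3268 and 1866 gene regions. Windows upstream of coding genes fell in 1873 cases (36.0%) and rose in 350, with a median of -0.37; with the miRNA total these were 763, 786 and 0.10. Arm windows had a median of -0.17, which turned to 0.31 with the miRNA total. Pseudogene and transposon gene windows rose in 1692 cases (15.0%) and fell in 169 (837 and 233 with DESeq2 size factors, 4660 and 48 with the miRNA total, 293 and 191 with all reads). The median of all windows was 0.14, and it was 0.62 with the miRNA total and -0.07 with all reads. The split depended on scaling: 2277 windows were lower and 11085 higher with the miRNA total, 7230 and 2444 with DESeq2 size factors and 6403 and 917 with all reads. For 21- to 22-nt reads 728 windows fell and 1100 rose (1248 and 261 with TMM factors), and the 1828 in all became 928 to 1673 with 1 library left out. In suvr2 replicate 2, 19.1% of all reads had 33 to 34 nt.

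Against frg1/2, suvr2 was lower in 3872 windows and higher in 5818 (4954 and 3172 with TMM factors, 5604 and 2383 with DESeq2 size factors, 1804 and 8487 with the miRNA total, 3675 and 1687 with all reads). The window upstream of PKS1 (chromosome 2, from 856501) had no read in suvr2 and 34.6 ± 1.66 CPM in frg1/2, at least 337-fold lower. Those upstream of AT5G20090 and NAC089 also had none, at least 268-fold and at least 179-fold lower. The window in ILA was higher in suvr2 (46.7 ± 3.64 CPM, 7.61 ± 0.30, adjusted p = 1.33e-29), as was one in AT5G43550 (53.7 ± 9.29 against 0.437 ± 0.352 CPM, 6.86).

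In drm1/2, 24-nt reads were lost upstream of many genes, while the number of pericentromeric windows that rose hung on the scaling, in the comparison that asks how 24-nt siRNAs depend on the methyltransferases DRM1 and DRM2. In the window from 22443501 on chromosome 1, upstream of the ferredoxin gene FED A (AT1G60950), no read was left of 59.7 ± 3.29 CPM in wild type, at least 653-fold lower. MYB74 (AT4G05100), whose upstream region is a known RdDM target, fell from 108 ± 4.16 to 0.852 ± 0.0474 CPM (-6.96 ± 0.18, adjusted p = 5.16e-23). TAS3C (AT5G57735), a source of trans-acting siRNAs, fell from 57.2 ± 2.96 to 1.68 ± 0.0384 CPM (-5.08 ± 0.17, adjusted p = 2.86e-21). Of 21360 pericentromeric windows 10417 rose (48.8%) and 2661 fell with the library sizes used, 7040 and 3150 with TMM factors, 5676 and 2370 with the miRNA total and 3970 and 3023 with all reads. Their median was 0.60 (0.31 to 0.53 under the other scalings), and their summed reads were 1.22 times wild type per genome-matched read but 0.989 times per read of the whole library (exact p = 0.1 and 1.0).

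The defensin-like gene LCR27 (AT4G29300) kept 1 read against 988 in wild type, a ratio of 1058 (counting interval 189 to 41811), and the cytochrome P450 gene CYP71B23 (AT3G26210) kept 2 against 1504, a ratio of 805 (222 to 6652). GA3OX4 (AT1G80330), an enzyme of gibberellin synthesis, kept 3 reads against 1483, a ratio of 529 (181 to 2569). LIS fell to 0.149 ± 0.0232 CPM (-8.91 ± 0.27, adjusted p = 3.72e-22), and AT1G31380 (-9.32), AT5G48020 (-9.19) and AT5G09575 (-9.07) also fell. AT1G73400, AT5G15360 and AT5G09050 kept 2, 1 and 3 reads. Windows upstream of AT1G73400 and of XCP2, a xylem peptidase gene, had no read left and were at least 415-fold and 338-fold lower. ASY2 rose to 31.6 ± 7.81 CPM (5.51 ± 0.32, adjusted p = 1.19e-15), MEE65 (AT2G01280) from 1.65 ± 0.593 to 22.6 ± 3.04 CPM (3.80 ± 0.19, adjusted p = 4.67e-17) and AT2G13150 from 31.7 ± 4.03 to 181 ± 49.5 CPM (2.51 ± 0.16, adjusted p = 7.61e-15). NAC089 rose from 2 to 155 reads (a ratio of 72.4, 19.7 to 603), and AT5G20740 (5.06), AT4G30740 (3.04), AT5G35370 (2.78), AT1G57613 (2.77), AT3G09970 (2.56) and AT5G29580 (2.53) rose as well.

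Of 13 silencing machinery regions 5 fell in drm1/2 and MORC6 rose (2.60), the same adjusted over the list alone. CLSY4 fell from 9.60 ± 1.13 to 0.229 ± 0.221 CPM (-5.23, adjusted p = 7.36e-16), DCL4 from 40.5 ± 1.5 to 1.84 ± 0.618 CPM (-4.50, adjusted p = 3.83e-19), and SUVH9 (-5.36), NRPD2 (-4.30) and CLSY1 (-2.31) fell too. Of 11 RdDM-linked genes 4 fell, MYB74, FWA (-2.81, adjusted p = 1.76e-12), SNC1 (-1.88) and ROS1 (-0.93), and 3 rose, EPF2 (0.91), RPP4 (0.64) and HISN6B (0.48), the same adjusted over the list alone. All 3 transposon genes tested rose: AtMu1 from 43.6 ± 0.482 to 105 ± 8.13 CPM (1.27, adjusted p = 1.09e-09), CACTA1 (1.02) and EVD (0.65). Of 7 TAS loci TAS3C, TAS3A (from 30.7 ± 2.82 to 16.0 ± 2.91 CPM) and TAS1A (-0.41) fell and TAS1C rose (0.49). Of 6 genes with triggered siRNAs AT1G62930 fell (-4.02) and AT1G63080 rose (1.21), and of the mutated genes DCL3 fell and FRG1 rose. The counts for these lists were the same adjusted over the list alone, and in camera the smallest adjusted p was 0.454 (0.588 with an estimated correlation), for the transposon genes.

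In drm1/2, 10948 windows (29.1%) fell and 14579 (38.7%) rose, 9468 and 6206 of them by at least 2-fold, and 4847 gene regions fell and 4084 rose. Windows upstream of coding genes fell in 3332 of 5205 cases (64.0%), with a median of -1.65 (down to -1.94 with all reads), and pseudogene and transposon gene windows rose in 7271 of 11272 (64.5%, and 2906 with all reads), with a median of 0.77 (0.47 to 0.69 under the other scalings). Arm windows fell in 8287 cases and rose in 4162, with a median of -0.67. The median of all windows was 0.37, and it was 0.16 with TMM factors and 0.08 with all reads. The split turned with scaling: 11957 windows were lower and 10107 higher with TMM factors, 11939 and 10155 with DESeq2 size factors, 10291 and 8334 with the miRNA total and 11682 and 5815 with all reads. For 21- to 22-nt reads 3522 windows fell and 3198 rose (4112 and 1178 with TMM factors), and 3479 of 5296 windows (65.7%) with lower 24-nt reads were also lower for 21 to 22 nt, with medians of -2.72 and -2.22. In drm1/2 replicate 3, 12.5% of all reads had 33 to 34 nt.

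**Figure D5:**
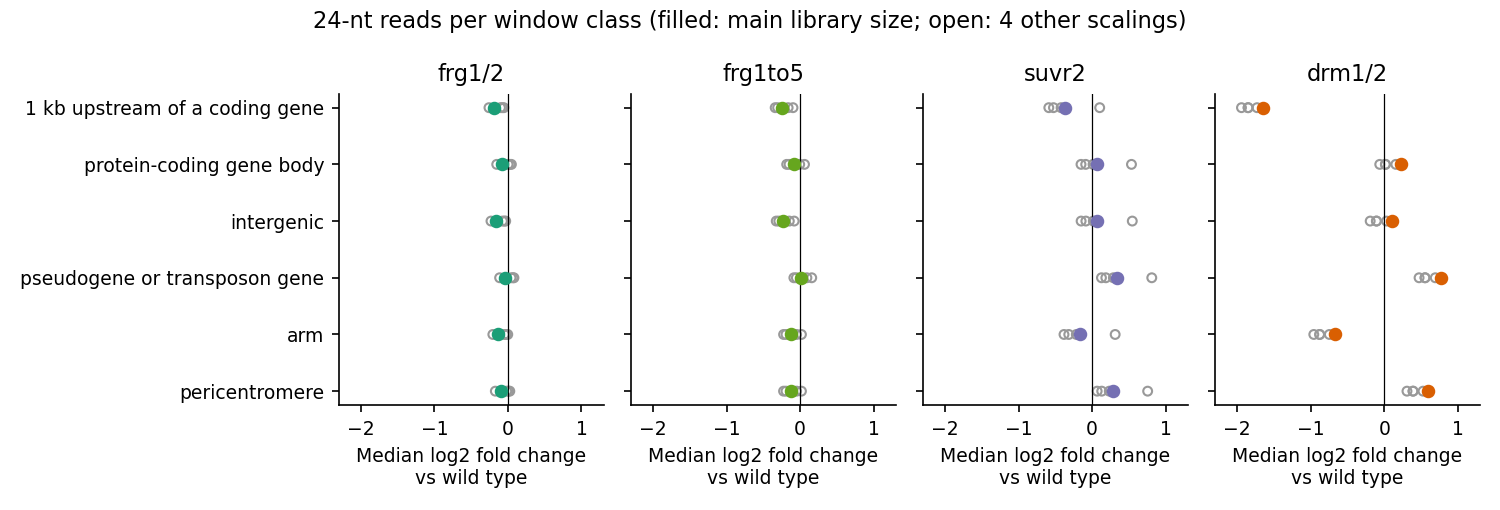
Median log2 fold change of 24-nt reads against wild type (x axis) of windows in 4 annotation classes, the arms and the pericentromeres (y axis) in 4 mutants (panels), filled for the library sizes used and open for 4 other scalings. Upstream windows were lowest in drm1/2 (-1.65) and its pericentromeric windows were at 0.60 (0.31 with all reads), while in suvr2 upstream windows went from -0.37 to 0.10 and arm windows from -0.17 to 0.31 with the miRNA total.

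Against frg1/2, drm1/2 was lower in 10089 windows and higher in 15193 (11626 and 8217 with TMM factors, 11458 and 8825 with DESeq2 size factors, 9895 and 6320 with the miRNA total, 10499 and 7915 with all reads). The window upstream of FED A had no read in drm1/2 and 38.5 ± 1.28 CPM in frg1/2, at least 422-fold lower, and the window in AT3G44580 from 16160501 on chromosome 3 was higher (128 ± 9.53 against 2.60 ± 0.192 CPM, 5.62 ± 0.21, adjusted p = 6.76e-32). Against suvr2, drm1/2 was lower in 9412 windows and higher in 7261 (10756 and 4193 with TMM factors, 12227 and 481 with the miRNA total, 8917 and 3266 with all reads). A window upstream of BGLU11 had no read in drm1/2 and 17.5 ± 1.88 CPM in suvr2, at least 189-fold lower. The window upstream of ASY2 was higher in drm1/2 (24.7 ± 6.73 against 0.194 ± 0.210 CPM, 7.08 ± 0.40, adjusted p = 2.90e-23), and one in MEE65 had 471 reads against 1.

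Most windows that lost 24-nt reads in frg1/2 also lost them in frg1to5, drm1/2 and suvr2, while under 1/2 of those called lower in drm1/2 or suvr2 were also called in frg1/2, by a test that recovered 48% of simulated 2-fold changes. Of the 3765 windows lower in frg1/2, 3224 (85.6%) were also lower in frg1to5, 3128 (83.1%) in drm1/2 and 2507 (66.6%) in suvr2. These made up 52.8% of the windows lower in frg1to5, 28.6% of those in drm1/2 and 43.3% of those in suvr2. Independent lists of these sizes would share 610, 1094 and 579. The covariance of log2 fold changes was 0.461, 0.543 and 0.289, and 0.0535, 0.0534 and 0.0531 in 10 simulations of unchanged groups against the same wild type libraries. The correlation was 0.758 with frg1to5, above the 0.476 of the simulations, but 0.344 with drm1/2 and 0.392 with suvr2, below their 0.492 and 0.479. Unchanged groups correlate through the shared control alone, and large changes in only 1 of the mutants lower a correlation. A correlation below the simulations therefore does not show that mutants are less alike than unchanged groups. Windows higher in both numbered 815 for frg1/2 and frg1to5 (63.3 if independent), 311 for frg1/2 and suvr2 (157), 460 for frg1/2 and drm1/2 (504), 804 for frg1to5 and drm1/2 (708) and 3468 for suvr2 and drm1/2 (1751). The lists behind these counts moved with scaling. Higher windows went from 14579 to 5815 in drm1/2 and from 4525 to 917 in suvr2 with all reads, and to 11085 in suvr2 with the miRNA total. Lower windows went to 1104 in frg1/2, 3992 in frg1to5, 2277 in suvr2 and 10291 in drm1/2 with the miRNA total, for which overlaps were not counted. Of 5793 windows lower in suvr2, 5460 (94.3%, and 49.9% of those lower in drm1/2) were lower in drm1/2 (1684 if independent, covariance 1.40 against 0.0533, correlation 0.661 against 0.502). Of 6106 lower in frg1to5, 4567 (74.8%, and 41.7% of those in drm1/2) were lower in drm1/2 (1775 if independent, covariance 0.702 against 0.0536, correlation 0.403 against 0.498). Part of each excess may come from the shared wild type libraries, which are too few to split. The values for independent lists were also taken over all windows together. Windows fell more often in the arms than in the pericentromeres in each of these mutants, which by itself raises the overlap of lower windows. Of the 1699 windows that fell at least 2-fold in frg1/2, 1061 were lower still in drm1/2 by the direct test, 193 were higher and 445 did not differ. For suvr2 these counts were 293, 358 and 1048, and for frg1to5 135, 94 and 1470. The median change of these windows from wild type, read on windows chosen in frg1/2, was -1.41 in frg1/2, -1.56 in frg1to5, -1.37 in suvr2 and -3.75 in drm1/2.

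The comparison of dcl3 asks what is left without the enzyme that makes 24-nt siRNAs: 24-nt reads fell and 21- to 22-nt reads rose across the genome with the library sizes used. Of 37670 windows 37113 (98.5%) had lower 24-nt reads and 77 higher, with a median of -3.41, and 10975 of 11448 gene regions were lower and 156 higher. For 21- to 22-nt reads 17096 of 18026 windows rose and 157 fell. Among windows with lower 24-nt reads that were tested for both, 16265 of 16860 (96.5%) rose for 21 to 22 nt, with a median of 2.29. So did 74 of 86 windows (86.0%) with unchanged and 63 of 67 (94.0%) with higher 24-nt reads, so the rise was not particular to windows that fell. The filter of 1 CPM in 3 libraries can be passed by the 3 dcl3 libraries alone, which favours windows that rise in dcl3. With TMM factors more windows fell than rose for 21 to 22 nt (below). SBT5.4 had no 24-nt read in dcl3 and 27.5 ± 5.09 CPM in wild type, at least 231-fold lower.

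AT3G27480, AT3G04717, AT1G34392 and AT5G67120 also had no read, at least 221-, 214-, 127- and 84.3-fold lower, and CML30 kept 1 read against 843 (a ratio of 703, 126 to 27817), AT1G08673 3 against 2012, AT1G73400 3 against 1376 and CASP 1 against 620. CNGC13 (AT4G01010), an ion channel gene, fell from 74.4 ± 3.92 to 0.162 ± 0.0710 CPM (-8.78 ± 0.32, adjusted p = 3.65e-20). The 4 regions that qualified as rises were AT5G20740 (3.26), AT3G09970 (2.65), NAC089 (35 reads against 2, a ratio of 21, 5.39 to 180) and VSP1 (AT5G24780), a vegetative storage protein (1.23 ± 0.31, adjusted p = 5.48e-04). AT5G20740 was also a named rise in every other mutant, AT3G09970 in frg1/2, suvr2 and drm1/2, and NAC089 in frg1/2, frg1to5 and drm1/2. All were compared with the same wild type libraries, and a difference between the wild type plants and the mutant stock was not tested. All 11 RdDM-linked genes, 3 transposon genes, 7 TAS loci and 6 genes with triggered siRNAs that were tested fell, as did 9 of 13 silencing machinery genes and DCL3 among 3 mutated genes, the same adjusted over the list alone. Examples are MYB74 (-3.59), TAS1C (-4.05), TAS2 (-4.65), AtMu1 (-3.59) and FWA (-4.11), with CLSY1 at 0 reads (at least 27.5-fold lower). Camera, which compares test statistics rather than fold changes, placed TAS loci below other regions and the silencing machinery, the triggered siRNA genes and the mutated genes above them (adjusted p = 0.0366, 0.0412, 0.0484 and 0.0366, and adjusted p = 0.0972, 0.104, 0.0972 and 0.0972 with an estimated correlation). The median of the TAS loci was -3.13 and that of all regions -3.43. The 24-nt reads over DCL3 itself were -2.25 with the library sizes used and 0.91 with TMM factors.

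With TMM factors, which set the bulk of windows level, dcl3 had 3587 windows lower and 1058 higher for 24-nt reads (3572 and 1073 with DESeq2 size factors) and a median of -0.26. TMM gave 2491 gene regions lower and 740 higher, and 2523 windows lower and 1586 higher for 21- to 22-nt reads. All annotation classes fell in 95.3% to 99.1% of their windows with the library sizes used. In dcl3 replicate 3, 14.9% of all reads had 33 to 34 nt, and without dcl3 replicate 2 the number of changed 21- to 22-nt windows went from 17253 to 11446, with fewer windows passing the filter. Against frg1/2, 37017 windows were lower in dcl3 and 69 higher (3313 and 1162 with TMM factors, 3137 and 1251 with DESeq2 size factors). The window from 16159501 on chromosome 3 at AT3G44570 was higher in dcl3 than in frg1/2 (20 ± 3.60 against 4.58 ± 1.85 CPM, 2.12 ± 0.22, adjusted p = 3.35e-13).

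For 21- to 22-nt reads over the gene regions of the lists, a count added after the data were seen, AT1G63080, a pentatricopeptide repeat gene with triggered siRNAs, rose in every mutant. It went from 26.8 ± 3.78 CPM in wild type to 70.9 ± 5.93 in frg1/2 (1.40, edgeR adjusted p = 1.91e-06), 66.5 ± 7.68 in frg1to5 (1.31), 80.5 ± 4.10 in suvr2 (1.59), 89.5 ± 18.4 in drm1/2 (1.74) and 83.1 ± 11 in dcl3 (1.63). All these comparisons use the same wild type libraries, so they are not independent, and a difference of the wild type plants was not tested. In dcl3 the rise lay below the median of all 21- to 22-nt windows (2.24). AT1G63080 was the only member called in its list of 13 tested in frg1/2, frg1to5 and suvr2 (5 in suvr2 adjusted over the list alone), while 4 rose in drm1/2 and 9 in dcl3. SUVH9 fell in frg1/2 (-2.75), frg1to5 (-2.47), suvr2 (-2.54) and drm1/2 (-2.71), and DCL4 fell in frg1to5 (-0.82) and drm1/2 (-2.79), where AGO4 rose (1.21), among 9 silencing machinery genes. No RdDM-linked gene, mutated gene, transposon gene or TAS locus was called in frg1/2 or frg1to5. In suvr2 FRG1 fell (-2.53), on only 1, 0 and 1 reads against 4, 7 and 3 in wild type, and ALN, 1 of 8 RdDM-linked genes, rose (0.97). In drm1/2 DCL3 (-1.98) and MYB74 (-4.88) fell, and AtMu1 (1.13), 1 of 2 transposon genes, and TAS1C (0.51), 1 of 7 TAS loci, rose (no TAS locus adjusted over the list alone). The fall of DCL3 in drm1/2 rested on 0, 2 and 2 reads against 5, 7 and 4 in wild type. In dcl3, DCL3 (3.55), all 8 RdDM-linked genes, both transposon genes, 7 of 9 silencing machinery genes and 3 TAS loci (2 adjusted over the list alone) rose. Of these, TAS1C (0.42), TAS3B (0.65) and TAS3C (0.72) were -1.55, -1.32 and -1.25 with TMM factors. Camera placed the triggered siRNA genes above other regions in frg1/2 (adjusted p = 0.0357, and adjusted p = 0.505 with an estimated correlation) and suvr2 (0.0242 and 0.646), and in dcl3 below them with the TAS loci (0.00256 and 0.0137, both 0.2 with an estimated correlation).

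Of the listed miRNAs, few passed the threshold in any mutant. Of 41 tested, miR157a was higher in drm1/2 (933 ± 121 against 517 ± 61.8 CPM, 0.85 ± 0.21, edgeR adjusted p = 0.0354), and this call was lost without wild type replicate 1, 2 or 3, without drm1/2 replicate 1 or 2, with the replicate block, and with 3-prime variants counted. None of the 41 passed in frg1/2, frg1to5, suvr2 or dcl3 in edgeR, with 0, 3, 2 and 4 at an unadjusted p below 0.05 and 6 in drm1/2. The DESeq2 Wald test called none in frg1/2, frg1to5 and suvr2, 4 in drm1/2 and 1 in dcl3. With the genome-matched total as library size 5 were higher in drm1/2 and 4 in dcl3, and without the 3 libraries rich in 33- to 34-nt reads 6 changed in drm1/2 and 1 in dcl3. Without frg1to5 replicate 1, 1 passed in frg1to5. By list, none of 18 development, 10 young, 5 silencing and 8 stress miRNAs passed in frg1/2, frg1to5, suvr2 or dcl3, also when adjusted over the list alone. In drm1/2, 1 development miRNA (miR157a) was higher, also when adjusted over the list alone, where 1 silencing miRNA, miR162a (-0.67, adjusted p = 0.0680 over all 41), was lower.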

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

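Chosen after the results had been seen were the tests of AT3G44570 and AT3G44580, of the drm1/2 library total, and of the windows higher in 4 mutants, while the test of repeat copies in drm1/2 was chosen before.

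Reads of 33 to 34 nt, which no comparison used, made up 19.1% of all reads in suvr2 replicate 2, 12.52% in drm1/2 replicate 3 and 14.93% in dcl3 replicate 3, against 2.11% to 3.05% in the wild type libraries and 1.49% to 5.68% in the other 15 libraries. Of these reads, 50.3% to 57.9% matched tRNA genes in the 3 libraries, 34% to 44.5% in wild type and 22.7% to 49.3% in all of the other 15. The same 3 libraries held 807 to 1099 reads of miR164a, and the other 15 held 27 to 710. No explanation of these libraries was tested.

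Both frg groups lost most 24-nt reads over AT3G44570 and AT3G44580. Differences from the reference that leave 1 mismatch per read did not account for it, since 24-nt reads with 1 mismatch in the span were at most 3.057 CPM in the 6 frg libraries and at least 27.3 in wild type. The 21-nt reads with 1 mismatch were 26.7 ± 7.49 CPM in frg1/2, 42.3 ± 16.0 in frg1to5 and 40.8 ± 14.8 in wild type. Reads with more mismatches were not counted, so denser differences from the reference stay open. A deletion of the whole span did not account for the loss, since 5.097% to 7.33% of the wild type level was left. The lowest share left in frg1/2 was 0.256%, among windows with at least 50 CPM in wild type. A deletion of a part, or another change carried by the line, may still be the reason, as 3.05% to 14.2% was left in the windows that lie wholly within the span. In suvr2 and drm1/2 the span kept its 24-nt reads, and no biological explanation was tested.

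In drm1/2, pericentromeric 24-nt reads were 1.22 times wild type per genome-matched read (3 libraries above every wild type library, exact two-sided p = 0.1), while those of the arms were 0.826 times. Losses elsewhere could raise this share by shrinking the library total. Per miRNA read the ratio was 1.222, but only 2 of the 3 libraries were above wild type (exact p = 0.6), and per read of the whole library it was 0.989 (exact p = 1.0), so the gain and the shrunken total cannot be told apart. Reads shared between repeat copies did not account for it, since counting them 1/n gave a ratio of 1.223. For suvr2 the ratios were 1.15, 1.62 and 0.984 in the same order.

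Among the 37670 windows, 44 were at least 2-fold higher in each of frg1/2, frg1to5, suvr2 and drm1/2. Independent lists would share 0.0906, but frg1/2 and frg1to5 share the FRG1 and FRG2 mutations. Chance from the shared wild type libraries stays open: the highest number in 10 simulations of unchanged groups was 0, but such groups hold no called windows to share, so this count decides nothing. Reads shared between repeat copies did not account for most of them, as 33 passed in all 4 groups with reads counted 1/n, and 37 did with TMM factors. A difference between the wild type plants and the stock of the mutants could give such windows, and it was not tested.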

How the results depend on the processing

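The fits without the 3 libraries rich in 33- to 34-nt reads, and the 21- to 22-nt gene regions of the lists, were added after the data were seen. Of 498 named features, 450 kept their direction and their side of the threshold under every alternative; of 6040 values, 5911 kept them, 103 were weaker (77 of these on leaving out 1 replicate), 20 stronger and 6 reversed. Of 421 values for 35 main results, 353 stayed within the limits set for each kind of value and 68 moved. Depth limits features near 0.241 to 0.479 CPM, the level of 3 counts. Except where the setting itself tests other windows or sets their bulk level, the cause was not tested.

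Reversed were DCL3 in dcl3 (0.91 with TMM factors), ROS1 in frg1/2 (-0.15 with reads counted 1/n), 21- to 22-nt reads in dcl3 of AT2G39675 (-1.55), AT5G49615 (-1.32) and AT5G57735 (-1.25) with TMM factors, and miR161.1 in dcl3 (0.63 with the genome-matched total).

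A minimum fold change of 2 left 2459 24-nt windows in frg1/2, 4000 in frg1to5, 4651 in suvr2 and 15674 in drm1/2 against wild type. It left 715 in frg1to5, 4395 in suvr2 and 16050 in drm1/2 against frg1/2, 9387 in drm1/2 against suvr2, and overlaps of 1349, 1099, 1463, 2369 and 3125 windows. TMM factors, which set the bulk of windows level, gave dcl3 4645 windows against wild type and 4475 against frg1/2, 4109 windows of 21 to 22 nt and 3231 gene regions, and DESeq2 size factors 4645 and 4388 windows. The miRNA total gave 1906 windows in frg1/2, 4676 in frg1to5, and against frg1/2 763 in frg1to5 and 16215 in drm1/2. All reads gave 638 in frg1to5 and 5362 in suvr2 against frg1/2. Reads counted 1/n, with more windows tested, gave 7634 in frg1/2, 12005 in frg1to5, 25378 in drm1/2 against suvr2, and for 21 to 22 nt 10716 in drm1/2 and 30407 in dcl3. No filter, with more windows tested, gave 548 in frg1to5, 983 in suvr2 and 30754 in dcl3 for 21 to 22 nt. Without the 3 libraries, dcl3 had 11012 such windows, with fewer tested, and 6 miRNAs changed in drm1/2 and 1 in dcl3. The genome-matched total gave 5 miRNAs in drm1/2 and 4 in dcl3, and the DESeq2 Wald test 4 and 1. The difference in 24-nt share was -1.76 (frg1/2), -2.18 (frg1to5), -5.07 (suvr2), -8.37 (drm1/2) and -35.4 points (dcl3) of all reads, 2.99 (suvr2) and -62.9 (dcl3) of 21- and 24-nt reads, and -1.97 (suvr2) and -61.6 (dcl3) of single-match reads.

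Leaving out 1 replicate gave 730 to 1117 windows for frg1to5 against frg1/2, and for 21 to 22 nt 298 to 480 in frg1/2, 509 to 869 in frg1to5, 928 to 1673 in suvr2 and 11446 to 17091 in dcl3. These counts moved over 1.5-fold without frg1/2 replicate 2 or frg1to5 replicate 3 for the first. For 21 to 22 nt they did so without wild type replicate 1 or 2 or frg1/2 replicate 1, without wild type replicate 1 or 2 or frg1to5 replicate 2 or 3, without wild type replicate 3 or suvr2 replicate 2 or 3, and without dcl3 replicate 2. It gave 0 to 1 miRNAs in frg1to5 (1 without frg1to5 replicate 1) and 0 to 1 in drm1/2. The replicate block left 0 miRNAs in drm1/2 and 3 named features weaker, and moved no other count over 1.5-fold. The libraries share only a replicate number, and correlations within numbers were -0.0772 to 0.0811, none above 0.1 for all pairs.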

Other observations

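The windows shared by all 4 mutants and the counts for other splits of the libraries were chosen after the results were seen, and the test of distance to FRG1 and FRG2 before. The largest window higher in frg1/2, frg1to5, suvr2 and drm1/2 lay in the pseudogene AT1G64035 (chromosome 1, 23755501 to 23756000), with 0.488 ± 0.0660 CPM of 24-nt reads in wild type, 86.2 ± 10.9 in frg1/2, 79.2 ± 4.94 in frg1to5, 12.3 ± 2.04 in suvr2 and 2.14 ± 0.870 in drm1/2. The next, in the pseudogene AT3G42645 (chromosome 3, 14730501 to 14731000), had 10.4 CPM in wild type and 26.6, 37.9, 21 and 41.2 CPM. A window near UGT71B8 had no read in wild type and 15.4 CPM in frg1/2. Of the 44 windows, 14 lay in coding genes, 13 were intergenic, 10 lay in pseudogenes or transposon genes and 7 upstream of coding genes, and 24 were lower and 2 higher in dcl3. At least 2-fold lower in all 4 mutants were 956 windows. Independent lists would share 3.26, but the mutants share wild type libraries, and frg1/2 and frg1to5 share the FRG1 and FRG2 mutations. Lower windows were also more frequent in the arms in each of these mutants, which independent lists over all windows leave out. All 956 were lower in dcl3, as were 98.5% of all windows tested.

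In frg1/2, windows changed at least 2-fold were tested for lying near the mutated genes, a prediction written before the value was seen. Chromosome segments carried along with the mutations would place them within 1 Mb of FRG1 or FRG2 at a ratio of 1.5 or more. Of 2459 such windows 86 (3.497%) lay there, against 652 (1.73%) of all tested windows, a ratio of 2.02 that met the prediction. Windows lower in suvr2 and drm1/2 had ratios of 2.13 and 2.13 at the same places, a comparison added after the value was seen, so carried segments and a region prone to losses cannot be told apart. Windows higher in frg1/2 and frg1to5 had ratios of 2.05 and 1.82 (27 and 26 windows), and those higher in suvr2 and drm1/2 0.512 and 0.531. These ratios do not decide it either. FRG1 and FRG2 lie in chromosome arms, while most windows called higher in suvr2 and drm1/2 were pericentromeric, and no ratio was computed within the arms alone. Windows that fell in frg1/2 were likewise more frequent in the arms than in the pericentromeres (above). This can raise the ratio in frg1/2 without carried segments, so meeting the prediction does not show them.

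Other splits of the 6 libraries of each comparison, a count made after the results were seen, are 10 with the real split, too few for a share under 0.05. Every other split also mixes both genotypes in each of its groups, so real differences become spread within groups and few features can pass. The low counts of the other splits were thus largely fixed in advance. For each of the 24-nt windows, 21- to 22-nt windows and 24-nt gene regions, 1 of the 10 splits, the real split, gave the largest count. For 24-nt windows the real count and the highest other were 5068 and 0 in frg1/2, 7935 and 1 in frg1to5, 10318 and 0 in suvr2, 25527 and 0 in drm1/2 and 37190 and 0 in dcl3 against wild type. Against frg1/2 they were 1245 and 30 in frg1to5, 9690 and 0 in suvr2, 25282 and 0 in drm1/2 and 37086 and 2 in dcl3, and drm1/2 against suvr2 gave 16673 and 0. For 21- to 22-nt windows they were 547 and 1 in frg1/2, 948 and 1 in frg1to5, 1828 and 0 in suvr2, 6720 and 0 in drm1/2 and 17253 and 0 in dcl3. For 24-nt gene regions they were 2537 and 0, 3663 and 1, 5134 and 0, 8931 and 0, and 11131 and 0 in the same order. For miRNAs, all 10 splits were as large as the real count of 0 in frg1/2, frg1to5, suvr2 and dcl3 (highest other 0, 0, 0 and 2), and 2 of 10 as large as the 1 in drm1/2 (highest other 1).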
